A study of Homo sapiens and Mus musculus with 6 samples.

How the data were processed

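RNA was measured in single cells of 5 libraries, 2 from human breast tumour, 2 from human pancreatic tumour and 1 from mouse breast tumour, and chromatin accessibility in 1 library of mouse breast tumour. Tumours were minced and digested with collagenase, red cells were lysed, and suspensions were labelled with hashtag antibodies before droplet capture, without sorting. The deposited RNA matrices hold counts of UMIs per gene and cell barcode with no normalization, for 33538 human or 31053 mouse genes and 10 hashtag antibodies, and only for barcodes called as cells. The deposited ATAC matrix holds counts per peak and cell barcode, and 91.0% of its values were even, as counts of transposase cut sites would be. Per the file headers, the RNA matrices were written by version 4.0.0 and the ATAC matrix by version 1.1.0 of the Cell Ranger software family. Processing notes also name STAR 2.7.0, Seurat 3.1 and 3.1.1 and the GRCh38 and mm10 builds. The annotation behind the gene identifiers is not given in the sources used here.

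The breast matrices held 5617 and 5897 barcodes, the pancreas matrices 1704 and 1857, and the mouse matrix 12266. Cells with fewer than 300 genes (86, 83, 79, 106 and 638 barcodes, in the order breast 1, breast 2, pancreas 1, pancreas 2, mouse) or more than 20% mitochondrial UMIs (769, 742, 256, 253 and 254) were left out. Scrublet scores from scanpy 1.11.5 ranked barcodes as doublets, and the highest were removed at a rate of 0.8% per 1000 barcodes of the library (214, 239, 19, 22 and 1116), since the automatic threshold marked only 1 barcode of the mouse library. Median genes per cell used were 836, 892, 2263.5, 2372 and 664. Human libraries were analysed together and the mouse library apart, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9). A cluster was given the class whose markers scored highest among 16 classes, where at least 3 markers exceeded the other clusters by a log2 fold of 1.5 with detection in 10% of cells. Clusters without a clear class were left unnamed. Other software was python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

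Samples were counted first. The libraries of a tissue were compared gene by gene over cells of 1 class (two-sided z of the UMI sums with the variance between cells, Benjamini-Hochberg, adjusted p of 0.05, genes with at least 50 counts), with a chi-square test of class counts and a count of shared barcodes (10 in breast and 1 in pancreas). A tissue counted as 1 sample if under 1% of genes differed in fibroblasts and in the largest other class. The check was tested on simulated data: with the fibroblasts of 1 library split at random and 200 genes lowered 4-fold on one side, it found 55.0% of them in breast and 84.0% in pancreas, and 0 genes without that change.

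UMIs were summed over the cells of a class, scaled to CPM by their total, and compared as log2 ratios after adding 1 CPM, in each class with at least 50 cells in every human library. Since each tissue had 1 sample, no test between tissues was made. Named genes had at least 50 CPM in 1 tissue and a log2 ratio of at least 1 in size with the same sign in every pair of libraries, and the 10 largest in each direction by the smallest pair ratio were taken. A named gene also had to be at least as high in the class as in the remaining cells of the same library on its higher side, as a guard against free RNA. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T-cell receptor genes, sex-linked genes of a fixed set and names made only of a clone or accession were left out by the rule, and genes whose presence or copy number differs between people were left out of naming after the data had been seen. Other members of the gene lists are given as examples. On simulated data the rule, run without the guard, found 31.3%, 89.6% and 98.5% of fibroblast genes changed by a fold of 2, 4 and 8. Those data were Poisson counts from 1 pooled profile, with no variation between cells or people and no free RNA. A gene with 0 counts on 1 side is given as at least so many fold higher, against a floor of 3 counts over the summed group, and a gene with 1 to 3 counts as a ratio with its counting interval. Intervals of sums are exact Poisson and intervals of shares exact binomial, at 95%. Those of list medians are from Poisson draws of the summed counts. The interval of the slope of stress genes on depth is from 200 redraws of cells with replacement. Gene positions are from the RefSeq annotation of GRCh38 (GRCh38.p14).

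The 25 gene lists covered fibroblast states, matrix, signalling responses, positional identity, stress, cell cycle and RNA of other cell types. A member counted as measured at 5 CPM or more in 1 tissue. Each list median was placed among 10000 random lists of the same size matched on mean expression, as a description, since genes of a list are not independent. Scores of 3 fibroblast lists were computed per fibroblast after thinning to 1000 UMIs, with 225, 248, 639, 734 and 1002 cells deep enough, and correlated across cells against 200 pairs of random lists. Mouse fibroblasts were clustered again at resolution 0.3, and for each subcluster the 50 genes of highest fold were matched to human by symbol and their mean pairwise correlation in human fibroblasts was placed among 10000 random lists. Mouse and human sums were compared over matched genes of at least 5 CPM, with 2232933 UMIs in mouse, 819035 in breast and 12444136 in pancreas fibroblasts. In that comparison CPM was scaled to these totals of matched genes instead of the class total. ATAC cells with at least 1000 counts were clustered on 20 components at resolution 0.5 after weighting peaks by how rarely they were open. The first component, with an absolute correlation of 0.987 with log depth, was left out. The highest such value among the kept components was 0.491.

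Alternatives tried were median-of-ratios size factors of the DESeq2 type (computed with numpy), no filter on low counts, no guard, a pseudocount of 5, leaving out each library, stricter cells (at least 1000 genes and at most 10% mitochondrial UMIs), doublet calls kept, resolution 2, fibroblasts with at least 2 UMIs of COL1A1, COL1A2, COL3A1 or DCN and none of EPCAM, PTPRC or PECAM1, and changes to thinning, scores, genes per subcluster and minimum values. Fibroblasts of each breast hashtag group, fibroblasts thinned to 1000 UMIs, named genes of other classes without each library in turn, and mouse subclusters, or mouse fibroblasts, without the subclusters holding at least 3 lymphocyte markers were added after seeing the data. Hashtag counts were not used to assign cells to people.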

Results

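The series set out to describe cancer-associated fibroblasts across tumour types and species. Unsorted tumours were digested to cell suspensions, and RNA was counted in single cells with droplet libraries of the 10x 3′ v3 type. There were 5 RNA libraries: 2 from human breast tumour, 2 from human pancreatic tumour and 1 from an endogenous breast tumour of Black 6 mice. Chromatin accessibility was measured by single-cell ATAC-seq in 1 further library, also from mouse breast tumour. Human breast libraries 1 and 2 held 15881695 and 18406434 UMIs (unique molecular identifiers, counts of RNA molecules), human pancreas libraries 1 and 2 held 12091917 and 13203958, and the mouse library held 26066870. After filtering, 4548 and 4833 breast cells, 1350 and 1476 pancreas cells and 10258 mouse cells were used. Cells of the pancreas libraries were deeper, with median counts of 6879.5 and 7332.5 UMIs per cell against 1597 and 1729 in breast and 1506.5 in mouse.

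The labels did not say whether the 2 libraries of a human tissue came from separate people. In breast, 0 of 3256 fibroblast genes and 44 of 11445 epithelial genes (0.384%) differed between libraries at an adjusted p of 0.05. In pancreas, 0 of 11346 fibroblast genes and 0 of 3856 T or NK (natural killer) cell genes differed. Class counts differed between the breast libraries (chi-square 32.4, 9 degrees of freedom, p = 0.000173) and not between the pancreas libraries (chi-square 5.98, 8 degrees of freedom, p = 0.65). By the rule fixed before the data were examined, the 2 libraries of a tissue therefore counted as 1 sample. Each tissue has n = 1, no replicate error exists for differences between tissues, and no p-value is given for them. All intervals are 95% intervals and cover counting error only, except that of the slope on depth given further below. That one comes from 200 redraws of cells and covers variation between cells.

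Which cell types made up each tumour was the first question. Fibroblasts were the largest class in the pancreatic tumour, at 49.3% of 2826 cells (47.5 to 51.2%, exact binomial), and made up 7.41% of 9381 cells (6.89 to 7.96%) in the breast tumour. Epithelial cells, the class that holds carcinoma cells, were 41.0% of breast cells (40.0 to 42.0%) and 0.354% of pancreas cells (0.170 to 0.650%). Macrophages, monocytes and dendritic cells were 27.1% of breast cells (26.2 to 28.0%) and 8.67% of pancreas cells (7.66 to 9.77%). T or NK cells were 14.4% of breast cells (13.7 to 15.1%) and 27.8% of pancreas cells (26.1 to 29.5%). Pericytes or smooth muscle cells, which surround vessels, were 1.39% and 4.95% of breast and pancreas cells. Endothelial cells, which line vessels, were 3.28% and 0.672%. B cells were 0.938% of breast and 2.69% of pancreas cells, and plasma cells were 0.373% and 1.34%. No acinar cells, the enzyme-secreting cells of the pancreas, were found among the 2826 pancreas cells. In the mouse tumour B cells made up 28.7%, T or NK cells 27.0%, plasma cells 15.2%, fibroblasts 10.1% (9.51 to 10.7%) and epithelial cells 4.43% of cells. No endothelial cells were found among the 10258 mouse cells, but with doublet calls kept 59 of 11374 mouse cells (0.519%; 0.395 to 0.669%) were endothelial. Clusters with no class name held 3.32% of breast, 4.18% of pancreas and 0.887% of mouse cells. Most such breast cells were in cluster 18 (93 and 109 cells of the breast libraries), whose closest class was endothelial and whose leading genes included CALCRL, SOX18 and CD34, so the breast endothelial share leaves these cells out. Most such pancreas cells were in cluster 23 (36 and 43 cells of the pancreas libraries, 25 and 22 of the breast libraries), whose closest class was macrophages, monocytes and dendritic cells and whose leading genes included S100A8, LYZ and IL1B, so the shares of that class leave them out. Fibroblast shares of the separate libraries were 7.32% and 7.49% in breast and 47.9% and 50.6% in pancreas. T or NK cells were 12.6% (11.7 to 13.6%) and 16.1% (15.0 to 17.1%) in the breast libraries, and macrophages, monocytes and dendritic cells 28.7% and 25.6%. Shares depended on the filter on cells. With at least 1000 genes and at most 10% mitochondrial UMIs, T or NK cells were 0 of 826 and 1 of 961 cells in the breast libraries, 13.5% and 11.8% in the pancreas libraries and 7.47% in mouse. Breast epithelial cells were then 68.8% and 65.6%, breast macrophages, monocytes and dendritic cells 17.1% and 19.3%, and mouse fibroblasts 34.3%. B and plasma cells were then 0 in both breast libraries, while B cells were 2.17% and 2.21% and plasma cells 1.41% and 1.11% in the pancreas libraries.

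**Figure D1:**
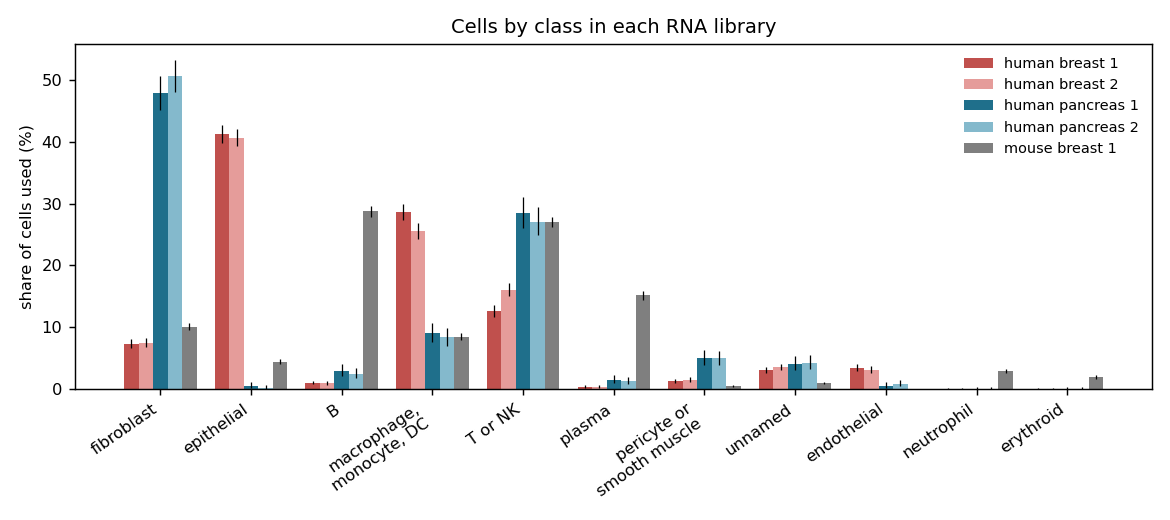
Share of the cells used (%) by cell class in each of the 5 RNA libraries, with exact binomial 95% intervals as lines. T or NK cells are 12.6% and 16.1% in breast libraries 1 and 2, and fibroblasts range from 7.32% in breast library 1 to 50.6% in pancreas library 2.

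Whether fibroblasts carry the same genes in both human tumour types was the main comparison, over 1394 pancreas fibroblasts (16703672 UMIs) and 695 breast fibroblasts (1097156 UMIs). The complement gene C7 (ENSG00000112936, GRCh38 chromosome 5, 40909497 to 40984643) was measured at 1718 CPM (UMI counts scaled to the class total; 1698 to 1738, exact Poisson) in pancreas and 28.3 CPM (19.2 to 40.1) in breast fibroblasts, a log2 ratio of 5.88. PTGDS, which encodes prostaglandin D synthase, was at 2757 CPM in pancreas and 123 CPM in breast, a log2 ratio of 4.47. In the other direction, the stromelysin MMP11 (ENSG00000099953, chromosome 22, 23772849 to 23784316) was at 22.3 CPM (20.1 to 24.7) in pancreas and 2463 CPM (2371 to 2557) in breast, a log2 ratio of -6.73. POSTN, the gene of the matrix protein periostin, was at 267 CPM (259 to 275) and 4860 CPM (4730 to 4992), a log2 ratio of -4.18.

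Other genes higher in pancreas fibroblasts included regulators of transcription. TCF21 (ENSG00000118526, chromosome 6, 133889113 to 133895537), a mesenchymal transcription factor, was at 92.8 CPM in pancreas with 0 counts in breast, which makes it at least 33.9-fold higher. The immediate-early gene ARC was at 78.1 CPM with 0 counts in breast, at least 28.6-fold higher. The orphan nuclear receptor NR4A3 was at 303 against 9.11 CPM (log2 ratio 4.91), and the pseudokinase gene TRIB1 at 190 against 6.38 CPM (4.70). The hyaluronan synthase HAS1 was at 224 against 3.65 CPM (5.60), with all 4 breast UMIs in library 2 and a log2 ratio of 4.85 or 7.82 without breast library 1 or 2, and the small heat shock protein HSPB6 at 273 against 17.3 CPM (3.90). The dipeptidase gene DPEP1 was 110-fold higher in pancreas (19.8 to 4361; 1 breast UMI, log2 ratios of 5.10 and 6.67 with 1 breast library left out), and the bradykinin receptor BDKRB1 was 52.2-fold higher (14.4 to 431).

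Among genes higher in breast fibroblasts, the collagenase MMP13 was at 136 CPM in breast and 0.180 CPM in pancreas, 756-fold higher (254 to 3708). The gelatinase MMP9 was at 119 CPM with 0 counts in pancreas, at least 665-fold higher, and its 2 breast libraries were at 64.8 and 167 CPM. CEMIP, which takes part in hyaluronan breakdown, was at 52.0 against 1.80 CPM (log2 ratio -4.24). Genes of signalling peptides were also in this set, with GRP (gastrin-releasing peptide) at 118 against 2.99 CPM (-4.90) and GAL (galanin) at 52.0 against 0.539 CPM (-5.10). NRN1 was at 58.3 CPM with 0 counts in pancreas, at least 325-fold higher, and MEGF10 was 350-fold higher (115 to 1739). DERL3, also a marker of plasma cells, was at 52.9 against 0.419 CPM (-5.25). Remaining cells of the breast libraries carried NRN1 at 6.03 and 7.03 CPM and DERL3 at 7.93 and 7.86 CPM.

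**Figure D2:**
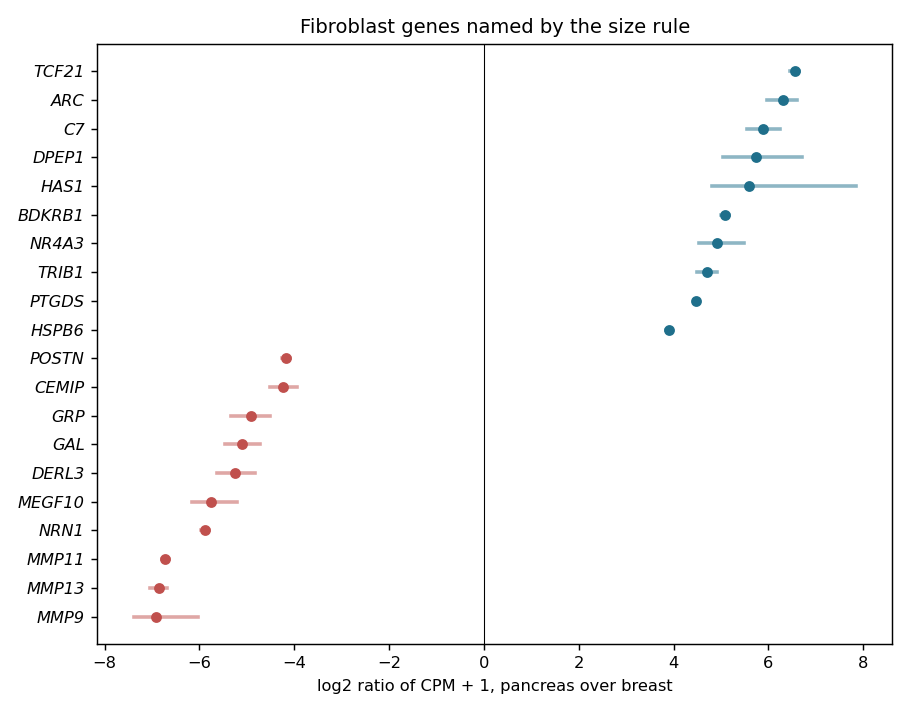
Log2 ratio of CPM + 1, pancreas over breast fibroblasts, for the 20 genes named by the rule, with lines for the range over the 4 pairs of libraries. All points lie beyond 1 or -1 in every pair of libraries, and genes with 0 counts in 1 tissue stand at the value the added 1 CPM gives.

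Immune-modulating fibroblast genes, a set of cytokines, chemokines and complement genes, were mostly higher in pancreas. Of 15 measured members, 11 were at least 1 log2 unit higher in pancreas and 1 was in breast, with a median log2 ratio of 2.75 (2.25 to 3.43; 2.30 to 3.25 over library pairs), or 3.79 against the first breast hashtag group (373 cells) alone. No random list of similar expression had a higher median. These values are over all fibroblasts. In cluster 14, which held fibroblasts of both tissues, the list's share of summed UMIs was higher in breast. It was 0.813% and 0.701% in breast and 0.400% and 0.280% in pancreas. This share is not a median of ratios, which was not computed within the cluster. Breast cells there were 84 and 105 (median 887.5 and 903 UMIs), and pancreas cells 22 and 28 (1373 and 2185 UMIs). Pancreas cells of cluster 3 had medians of 12529 and 12143 UMIs. Over all fibroblasts, the chemokine CCL19 was at 89.5 against 4.56 CPM (4.03) and CXCL2 had a log2 ratio of 3.43. CCL2 was at 563 against 169 CPM (1.73) and complement C3 at 1843 against 377 CPM (2.29). PTGS2, the inducible cyclooxygenase, was at 82.6 against 3.65 CPM (4.17). CXCL12, a chemokine for CXCR4-bearing cells, was close to equal (0.22), and CXCL14 was higher in breast, at 89.6 against 299 CPM (-1.73). Genes of the early response to tissue digestion and stress were higher in the same pancreas cells: 10 of 18 were at least 1 log2 unit higher and 0 lower, with a median of 1.48 (1.39 to 1.57). Among them FOSB was at 2061 against 233 CPM (3.14), SOCS3 at 471 against 45.6 CPM (3.34) and JUNB at 2.31 on the log2 scale, while the heat shock gene HSPA1A was at -0.72.

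Contractile and matrix-producing fibroblast genes were mostly higher in breast. Of 18 measured members, 11 were at least 1 log2 unit higher in breast and 0 in pancreas, with a median of -1.61 (-1.67 to -1.55; -1.70 to -1.50 over library pairs). No random list of similar expression had a lower median. Examples were CTHRC1, a secreted collagen-associated protein, at 752 against 2597 CPM (-1.79), COL11A1 at 248 against 1142 CPM (-2.20), the membrane protein LRRC15 at 18.8 against 139 CPM (-2.82) and tenascin C (TNC) at 19.5 against 219 CPM (-3.42). FAP, fibroblast activation protein, was at 192 against 477 CPM (-1.31). Smooth muscle actin ACTA2 was at 597 against 1048 CPM (-0.81), and the actin-binding TAGLN was at -0.29. All these values are over all fibroblasts. The summed list took 2.59% and 2.73% of UMIs in breast cells of cluster 8. In cluster 14, which held fibroblasts of both tissues, it took 0.618% and 0.560% in breast and 0.679% and 0.503% in pancreas. A difference in summed share was thus not seen there, over 22 and 28 pancreas cells. The median of ratios was not computed within the cluster.

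Steady-state fibroblast genes, typical of resting connective tissue, had 6 of 15 measured members at least 1 log2 unit higher in pancreas and 1 in breast, with a median of 0.82 (0.56 to 1.08; 0.56 to 0.91 over library pairs), or 2.06 against the second breast hashtag group alone. CCDC80 was at 3087 against 979 CPM (1.66), SEMA3C at 313 against 64.7 CPM (2.25) and the surface protein CD248 (endosialin) at 1.43, while PI16 was at 5.27 against 41.0 CPM (-2.74). Genes common to all fibroblasts had a median of 0.19, with 1 of 12 at least 1 log2 unit higher in pancreas. Collagen I was at like levels in both tissues, with COL1A1 at 19558 against 17444 CPM (0.16) and COL1A2 at -0.20.

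Interferon-response genes were higher in breast fibroblasts, with 13 of 15 at least 1 log2 unit higher there, 0 in pancreas and a median of -1.99. The ubiquitin-like ISG15 was at 184 against 1177 CPM (-2.67) and the antiviral gene MX1 at -2.48. Cell-cycle genes were also higher in breast, with 10 of 13 measured members at least 1 log2 unit higher and a median of -2.38, but against the second breast hashtag group (51 cells) alone their median was 0.78. Among matrix metalloproteinases and inhibitors, 8 of 16 were higher in breast and 4 in pancreas by that measure, with a median of -1.14. MMP14 was at -1.57 and TIMP3 at -1.51, against 3.31 for ADAMTS1 and 2.53 for MMP19. Fibrillar collagen and crosslinking genes had a median of -0.38 with 0 and 4 of 16 members higher in pancreas and breast, and examples were COL5A3 at -2.76 and LOXL2 at -2.37. Basement membrane genes had a median of -0.51, with COL15A1 at -2.05 and COL4A5 at 1.47.

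Transcription factors of body position, such as HOX genes, split between tissues: of 33 measured members 13 were at least 1 log2 unit higher in pancreas and 12 in breast, with a median of 0.20. GATA6 was at 1.88, WT1 at 2.32 and HOXA5 at 1.85, whereas HOXC6 was at -2.81 and HOXD8 at -3.20. With 0-count members held at the bound that 3 counts allow, 12 were higher in each tissue. Hypoxia genes had a median of -0.37, TGF-beta response genes -0.17 with 5 of 13 members higher in each tissue, and focal adhesion genes -0.13 with 2 of 17 members higher in pancreas and 0 in breast. Against the second breast hashtag group these were 0.44, 0.89 and 0.10, and thinning turned the medians of positional factors (-0.27) and TGF-beta response genes (0.22). TGFBI, a TGF-beta-induced matrix protein, was at -4.07. Genes of steroid hormone receptors and response had a median of 0.52, with 5 of 12 higher in pancreas, among them PER1 at 1.88 and IGF1 at 1.70.

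RNA of other cell types was measured in the same breast fibroblasts. Breast epithelial genes had a median log2 ratio of -4.72 (-5.11 at the bound of 0-count members), with 11 of 12 higher in breast, such as MUCL1 at 1.08 against 252 CPM. Cytotoxic lymphocyte genes had a median of -4.20 (-4.46 at the bound) with 9 of 9 higher in breast, and tissue-resident macrophage genes -3.16 with 5 of 7, or 0.44 against the second breast hashtag group alone. All 6 measured antigen-presenting genes were at least 1 log2 unit higher in breast, with a median of -1.56, among them CD74 at -2.72 and HLA-DRA at -3.06. Pancreatic ductal genes had a median of -0.96 over 4 measured members, T-cell exhaustion genes -0.82 over 3, endothelial tip cell genes -1.34 over 6 and lipid-associated macrophage genes 0.07 over 11 (-0.027 with thinning). No acinar gene reached 5 CPM in either tissue. Fibroblasts of the tissues were mostly in different clusters, with 246 and 253 breast cells of libraries 1 and 2 in cluster 8, and 493 and 563 pancreas cells in cluster 3. Cluster 14 held both, with 84 and 105 breast and 22 and 28 pancreas cells. Clustering had no correction for library or depth, and median UMIs per cell were 1597 in cluster 8 and 12243 in cluster 3. Median-of-ratios scaling moved the median log2 ratio of all genes in fibroblasts by 0.236 and gave medians of 0.11 for focal adhesion and 0.07 for TGF-beta response genes.

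The other classes of the same tumours were compared to see which differences were found outside fibroblasts. In T or NK cells (785 pancreas and 1350 breast cells; 1546987 and 964080 UMIs), interferon and cell-cycle genes were higher in breast and early-response genes higher in pancreas. All 15 interferon-response genes were at least 1 log2 unit higher in breast, with a median of -2.62, including ISG15 at 112 CPM in pancreas (96.4 to 130.5) and 1286 CPM in breast (1216 to 1360; log2 ratio -3.50). IFIT3 was at -4.59, RSAD2 at -4.17, PARP9 at -2.70 and EPSTI1 at -2.71. Of 15 cell-cycle genes, 13 were higher in breast, with a median of -4.11, or -3.92 with 0-count members at their bound. The proliferation marker MKI67 was 85.0-fold higher in breast (14.6 to 3422), UBE2C was at least 31.6-fold higher, and PCLAF was at -4.51, STMN1 at -3.46 and CKS2 at -3.46. Of 18 stress genes, 12 were at least 1 log2 unit higher in pancreas, with a median of 1.28, and JUN was at 3762 against 412 CPM (3.19).

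Other genes higher in pancreatic T or NK cells were the heat shock gene HSPA6 (4.10), the plexin PLXND1 (3.35), the phosphodiesterase PDE4D (3.12), SPRY1 (2.94), IER5 (2.73), NCR3 (2.56), which encodes the NK receptor NKp30, METRNL (2.55), PFKFB3 (2.44) and PHYH (2.39). Cytotoxic genes differed little, with a median of -0.32 and 1 of 11 members higher in each tissue, where GNLY was at -2.14 and PRF1 (perforin) at 1.03. Exhaustion genes had a median of -0.16, with CXCL13 at -3.38 and HAVCR2 at 1.13. Regulatory T-cell genes had a median of -1.09 with 4 of 7 higher in breast, including FOXP3 at -1.42 and TNFRSF4 at -1.82. Breast epithelial genes had a median of -6.04 in these cells, or -5.06 at the bound. Breast cells of this class were mostly in cluster 2 (489 and 688 cells) and pancreas cells in cluster 5 (354 and 363 cells), and the all-gene shift under median-of-ratios scaling was 0.0878.

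Macrophages, monocytes and dendritic cells numbered 245 in pancreas (1922555 UMIs) and 2540 in breast (3565818 UMIs). Most breast cells were in clusters 1 and 4, whose leading genes included C1QC, C1QA and TREM2. Most pancreas cells were in cluster 16, whose leading genes included FCER1A, LYZ and CD86 beside C1QC and CSF1R. The ratios below are for the class as a whole and do not separate a change within 1 cell type from a different mix of cells. SPP1, the gene of osteopontin, was at 252 CPM in pancreas (230.3 to 276) and 6630 CPM in breast (6545 to 6715; log2 ratio -4.71), and its pancreas libraries were at 55.6 and 446 CPM. MRC1, the mannose receptor of tissue macrophages, was at 701 CPM in pancreas and 16.3 CPM in breast (5.35). FCN1, which encodes ficolin 1, was at 4.36, the lectin CLEC10A at 4.97 and CD1C, which presents lipid antigens, at 3.85. The growth factor genes AREG and EREG were at 4.08 and 4.82, LYVE1 was at 4.68, the chitinase CHIT1 at 5.80, the decoy receptor IL1R2 at 3.67 and properdin (CFP) at 4.09. Higher in breast were IFI27 (-5.75), OLFML3 (-5.36), CXCL11 (-5.02), HTRA1 (-4.72), ADORA3 (-4.54), ITGA6 (-4.30), MMP2 (-4.16), IFIT1 (-4.14) and C3, which was at 56.2 against 1372 CPM (-4.59). For C3 the direction was the opposite of that in fibroblasts.

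Lipid-associated macrophage genes had 8 of 12 members at least 1 log2 unit higher in breast and 0 in pancreas, with a median of -1.27. APOE was at 509 against 7468 CPM (-3.87), APOC1 at -3.21 and TREM2 at -1.52. Tissue-resident macrophage genes had 5 of 11 higher in pancreas and 1 in breast, with a median of 0.22, among them FOLR2 (1.52), F13A1 (2.94) and SELENOP (2.16). Interferon genes were higher in breast in 13 of 15 (median -1.75) and cell-cycle genes in 14 of 16 (median -1.73). Stress genes were higher in pancreas in 6 of 18, with a median of 0.64, and breast epithelial genes had a median of -5.24, or -4.56 at the bound. Breast cells of this class were mostly in clusters 1 and 4, and pancreas cells in cluster 16 (111 and 109 cells). The all-gene shift under median-of-ratios scaling was 0.210.

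Pericytes or smooth muscle cells of both tissues shared cluster 11, with 140 pancreas cells (1043372 UMIs) and 130 breast cells (175705 UMIs). The cytokine IL6 was at 401 CPM (363 to 441) in pancreas with 0 counts in breast, at least 23.5-fold higher, and its pancreas libraries were at 596 and 210.2 CPM. CCL2 was at 1008 against 22.8 CPM (5.41; breast libraries 54.7 and 0 CPM), the metallothionein MT1A at 1056 against 22.8 CPM (5.48; pancreas libraries 1506 and 617 CPM, breast libraries 0 and 39.0 CPM) and the protease ADAMTS1 at 4.06. SLC7A5, COL4A5, GPAT2, CASP9, PTGER1 and CCL21 had 0 counts in breast and were at least 4.21-, 3.37-, 3.82-, 3.26-, 3.09- and 3.14-fold higher in pancreas, where CCL21 was at 77.6 and 30.3 CPM in the separate libraries. In breast, the bone sialoprotein IBSP was at 91.1 CPM with 0 counts in pancreas, at least 31.7-fold higher, GRP was at least 19.8-fold higher, and MMP9 was at 2.88 against 290 CPM, 101-fold higher (32.6 to 506), with breast libraries at 68.4 and 449 CPM. Also higher in breast were ADAM12 (-4.41), TNFAIP6 (-4.07), UNC5B (-3.96), MXRA5 (-3.58), P2RY14 (-3.39), SPON2 (-3.33) and OLFML3 (-3.03). Leaving out 1 library moved the ratio by over 1.5 times for 9 of the 20 named pericyte genes. The same was true of 8 of the 20 in macrophages and 6 of the 20 in T or NK cells. No direction could turn, since the naming rule asked for the same sign in every pair of libraries. The largest shifts were those of CCL2 and MT1A, which had 4 breast UMIs each and reached 9.98 and 10.05 without 1 breast library.

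Immune-modulating genes in pericytes had 7 of 9 measured members higher in pancreas, or 6 at the bound of the 5 members with 0 counts on 1 side. Their median was 5.40, or 1.43 at that bound. Fibrillar collagen genes had 11 of 16 members higher in breast (10 at the bound), with a median of -1.37, including COL1A1 at -2.41 and COL3A1 at -2.15. Genes common to all fibroblasts were also higher in breast in these pericytes, with a median of -1.82, 6 of 10 measured members higher in breast and 0 in pancreas. Basement membrane genes had a median of -1.20, interferon genes -1.28 with 11 of 15 higher in breast, contractile and matrix genes -0.62, and stress genes 1.51 with 13 of 18 higher in pancreas. Breast epithelial genes had a median of -5.34, or -3.78 at the bound. The all-gene shift under median-of-ratios scaling was 0.168. Of the 20 fibroblast genes named above, 7 of the 7 pancreas-higher and 5 of the 5 breast-higher genes measured in pericytes went the same way by at least 1 log2 unit. In macrophages this held for 4 of 4 and 2 of 4, and in T or NK cells for 2 of 4 and 2 of 2. The classes come from the same libraries and share their free RNA, so these counts are not independent of each other; POSTN and MMP11 were at 16.6 and 14.5 CPM in breast T or NK cells.

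**Figure D3:**
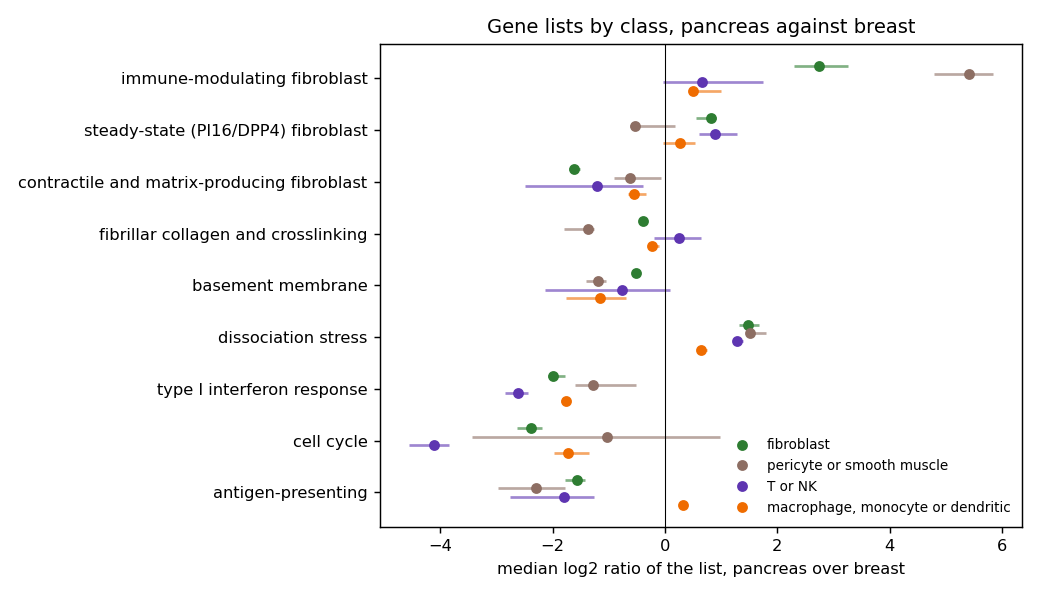
Median log2 ratio of CPM + 1, pancreas over breast, of 9 gene lists in 4 cell classes, with lines for the range over pairs of libraries. Interferon-response genes lie below 0 and stress genes above 0 in all 4 classes; the pericyte value of the immune-modulating list is 1.43 when 0-count members are held at their bound.

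Whether fibroblast states seen in 1 tumour recur in others was asked within each library. Fibroblasts with higher immune-modulating scores had lower contractile and matrix scores in every library once cells were thinned to 1000 UMIs. Spearman correlations across cells were -0.262 and -0.223 in breast, -0.353 and -0.393 in pancreas and -0.393 in mouse, all under the lower bounds from random lists (-0.152, -0.148, -0.117, -0.107 and -0.112). Without thinning they were -0.215, -0.182, 0.111, 0.0677 and -0.145, so the sign in pancreas turned with thinning. Steady-state and immune-modulating scores correlated positively in breast, at 0.341 and 0.330 against upper random bounds of 0.163 and 0.234, and were near 0 in pancreas (0.00301 and 0.0217) and mouse (-0.00935). Without thinning this pair was at 0.443 and 0.373 in breast, 0.393 and 0.339 in pancreas and 0.0672 in mouse, so the contrast between breast and pancreas was found only with thinning. Steady-state and matrix scores correlated at -0.172 and -0.262 in breast, -0.0290 and -0.00523 in pancreas and -0.182 in mouse. The values for breast library 2 and mouse lay under their random bounds of -0.137 and -0.0772. Without thinning these 5 values were -0.00276, -0.0358, 0.519, 0.496 and 0.114.

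Levels of the lists also differed between clusters, though not in the same way in every library. In breast cluster 8, matrix genes took 2.59% and 2.73% of UMIs in the 2 libraries and immune-modulating genes 0.0661% and 0.0730%. In breast cells of cluster 14 they took 0.618% and 0.560%, and 0.813% and 0.701%. In pancreas cluster 3 matrix genes took 0.884% and 0.875% and immune-modulating genes 0.566% and 0.579%, and in pancreas cluster 15 they took 0.322% and 0.316%, and 0.873% and 0.80%. Pancreas cells of cluster 14 lay below cluster 3 for both lists, at 0.679% and 0.503% for matrix and 0.400% and 0.280% for immune-modulating genes, as did pancreas library 2 cells of cluster 29 (0.695% and 0.343%). Mouse fibroblasts of cluster 10 had 2.75% of UMIs in steady-state, 0.549% in immune-modulating and 0.302% in matrix genes, against 1.52%, 0.737% and 0.528% in mouse cluster 5, so immune-modulating and matrix genes were both higher in cluster 5.

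**Figure D4:**
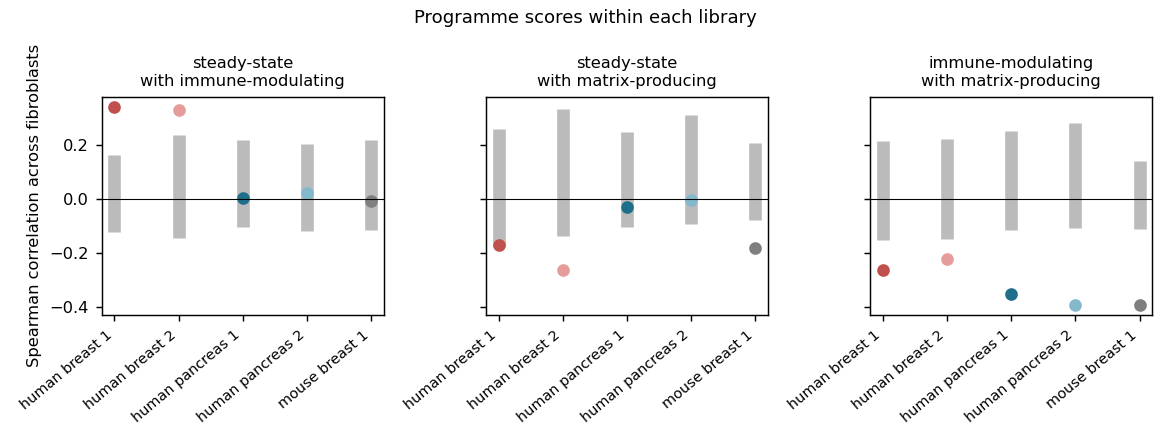
Spearman correlation across fibroblasts of each library between scores of 3 pairs of gene lists, with cells thinned to 1000 UMIs; grey bars give the middle range of random list pairs. Immune-modulating and matrix scores correlate negatively in all 5 libraries, from -0.393 to -0.223.

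Genes of mouse fibroblast subclusters were then followed into human fibroblasts, to ask whether states defined in mouse hold together in human tumours. Mouse subcluster 0 (343 cells) carried steady-state genes such as Pi16, Dpp4 and Sema3c (2.81% of UMIs), subcluster 1 (285 cells) immune-modulating genes such as Cxcl12 (1.29%), and subcluster 2 (243 cells) matrix genes such as Tnc and Lrrc15 (0.780%). The mean pairwise correlation of the subcluster 1 genes lay at the 100, 98.9, 99.97 and 99.85 percentiles of random lists in breast libraries 1 and 2 and pancreas libraries 1 and 2. With 25 genes they lay at 93.9, 56.6, 79.9 and 91.2, all under the upper random bound, and with 100 genes breast library 2 lay at 73.0, so this result depended on the number of genes. Subcluster 2 genes lay at 62.6 and 83.9 in breast and 99.9 and 99.95 in pancreas, and subcluster 0 genes at 18.4 and 94.2 in breast and 100 and 100 in pancreas. With 25 genes subcluster 0 lay at 96.0 in pancreas library 1, under the upper random bound. Subcluster 4 (39 cells) lay at 22.7 and 5.92 in breast and 99.4 and 99.2 in pancreas, where with 25 genes it lay at 86.0 and 62.5. Subclusters 3 (103 cells) and 5 (22 cells) carried B-cell and T-cell genes. They lay at 100 and 99.7, and at 100 and 100, in breast, and at 65.4 and 64.9, and at 71.8 and 94.9, in pancreas. Of 24 combinations of subcluster and library, 14 (58.3%) lay above the upper random bound, and with 25 genes per subcluster 7 of 24 (29.2%) did. Without subclusters 3 and 5, left out after their values were seen because they hold lymphocyte markers, these were 10 of 16 (62.5%) and 3 of 16 (18.8%).

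Mouse fibroblasts were compared with human fibroblasts over 15855 genes matched by symbol, to ask how far the species share a fibroblast profile. CPM values of this comparison are scaled to the UMIs of the matched genes only. Human values are therefore higher than those given above for the same genes and cells. The 1035 mouse fibroblasts include the 125 cells of subclusters 3 and 5, which carried lymphocyte genes beside fibroblast genes: medians of 139 and 95.5 UMIs per cell were of Col1a1, Col1a2, Col3a1 and Dcn, against 102 in subcluster 0. Without these cells, left out after their values were seen, fibroblasts were 8.87% of mouse cells (8.33 to 9.44%) instead of 10.1%. Among the 8 mouse classes with at least 50 cells, which leaves out mouse pericytes, fibroblasts were closest to the fibroblasts of each human library, with Spearman correlations across genes of 0.655 and 0.643 in breast and 0.645 and 0.645 in pancreas. Mouse epithelial cells came next, at 0.494, 0.471, 0.460 and 0.459. Genes are not independent replicates, and with genes of at least 50 CPM the fibroblast values were 0.384, 0.383, 0.363 and 0.365. Without the 125 cells they were 0.657, 0.645, 0.648 and 0.648. Steady-state genes were higher in mouse, with 14 of 15 members at least 1 log2 unit higher than in breast and 12 than in pancreas (medians 2.96 and 2.47). PI16 was at 1482 CPM in mouse, 54.9 in breast and 7.07 in pancreas, DPP4 at 224, 23.2 and 18.4, and CD34 at 1067, 29.3 and 51.0. Matrix genes were lower in mouse, with 15 of 18 lower than in breast and 9 lower and 4 higher than in pancreas (medians -3.11 and -1.29). COL11A1 was at 30.9 CPM in mouse, 1530 in breast and 332 in pancreas, and ACTA2 at 106, 1404 and 802.

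Immune-modulating genes in mouse fibroblasts lay between the human tissues, with medians of 1.85 over breast and -1.22 over pancreas. On the scale of matched genes, C3 was at 4095 CPM in mouse, 505 in breast and 2474 in pancreas, while C7 was at 1.34, 37.8 and 2306. Interferon genes were lower in mouse than in breast (9 of 12; median -2.02) and near pancreas (median 0.15). Fibrillar collagen genes had medians of 0.40 over breast and 0.83 over pancreas, basement membrane genes 0.53 and 1.02, and stress genes -0.22 and -1.53. Named genes higher in mouse included the acute-phase gene LBP (1171 CPM in mouse, 0 in breast, 2.73 in pancreas), PLA1A (737 CPM), PLAC8 (896 CPM), CRIP1 (2370 CPM) and ANXA3 (934 CPM). Without the 125 cells of subclusters 3 and 5 the rule named 9 of the same 10 mouse-high genes, all but ANXA3, and 10 of the same 10 human-high genes. The B-cell chemokine CXCL13 was at 183 CPM in mouse with 0 counts in both human tissues, at least 49.9-fold over breast and 758-fold over pancreas. SBSN, TMEFF2, OPCML and XDH were also higher in mouse, at 238, 124, 112 and 128 CPM. Higher in human were COL10A1, a collagen of hypertrophic cartilage, with 0 counts in mouse (928 CPM in breast and 166 in pancreas, at least 691- and 124-fold higher), and COMP, a cartilage matrix protein (280 and 359 CPM against 1.34). CYBRD1 (344 and 419 CPM), PDLIM3 (178 and 538), MYL6B (101 and 123), RTL8C (177 and 120) and RARRES1 (204 and 442) were also higher in human. CFD, PTGDS and GSTP1 were named as well, but how reads of the mouse genes and their relatives were counted is uncertain, and CFD and PTGDS had 0 counts in mouse fibroblasts.

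The mouse breast tumour ATAC-seq library held 4518 cells and 82584252 counts in 162916 peaks, with a median of 9000 counts per cell. Of these cells 3474 (76.9%) had at least 1000 counts and fell into 15 clusters. Depth was not fully removed from the clustering, since a kept component had an absolute correlation of 0.491 with log depth. Median counts per cell were 3532 in cluster 8 and 44569.5 in cluster 13. The peak with the largest log2 ratio over the rest, 6.57, was on chromosome 5 in cluster 14 (29 cells, 0.835%). Cluster 3 (319 cells, 9.18%), with a largest log2 ratio of 4.85, is given as an example of a larger cluster. A peak on mm10 chromosome 6, from 122652993 to 122655327, had 119 CPM (109 to 129) in cluster 3 and 3.15 in other cells, and was open in 69.9% of cluster 3 cells and 2.82% of others. Another on chromosome 2, from 19626954 to 19628741, had 78.4 CPM there and 1.92 elsewhere. No gene names were assigned to the peaks, since no annotation of mm10 was at hand, so accessibility was not compared with RNA.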

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

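Of the tests given here, the test of tissue handling was chosen only after the result was seen. The thinning tests were also chosen after seeing the data. Predictions for the thinning tests and for the remaining tests were written before their values were computed.

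Genes of steroid hormone receptors and response went opposite ways in 2 cell classes under the same comparison, with a median log2 ratio of -0.79 in macrophages, monocytes and dendritic cells and 0.52 in fibroblasts. That difference between classes was not tested. The hashtag antibody counts, which entered only the comparisons by hashtag group added later, held a strong signal on few of the 10 tags: 90.1% and 90.9% of tag UMIs lay on 2 leading tags in breast libraries 1 and 2, 96.7% and 96.3% on 1 tag in the pancreas libraries, and 99.8% on 3 tags in the mouse library. Whether the leading tags stand for separate people or animals is not given in the sources used here.

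Stress genes were higher in pancreas fibroblasts by a median log2 ratio of 1.48, and pancreas cells were deeper. With fibroblasts of both tissues thinned to 1000 UMIs the median was 1.70. Thinning keeps the expected gene shares of each cell, so it could hardly remove a difference tied to depth. It also left out 108 and 114 breast fibroblasts against 8 and 13 pancreas fibroblasts. The value of 1.70 therefore does not decide on depth. Free RNA could not be told from cell RNA: the list took 2.03% of UMIs in the third of pancreas fibroblasts with fewest UMIs (median 6743) and 1.68% in the third with most (median 16651), a slope of 0.213 per log2 unit of depth (0.156 to 0.276), under the bound of 0.25 at its centre but not over its interval. Handling of the tissue could also raise these genes in every class, and the lowest median over the 4 classes was 0.637, in macrophages; with 1 sample per tissue, handling and tumour type cannot be told apart, so the biological explanation stays open as well.

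Immune-modulating genes were higher in pancreas fibroblasts by a median of 2.75. If they were part of the stress response, they were predicted to be near equal in the least stressed cells. The median was 2.54 in the 458 pancreas fibroblasts with the lowest stress scores. Stress genes themselves still had a median of 0.95 over breast in those cells, so the test does not decide on the stress response. The median was not higher in the pancreas fibroblasts with the highest stress scores, at 2.39. With fibroblasts of both tissues thinned the median was 2.63. That value does not decide on depth, since thinning keeps the expected gene shares of each cell. In pancreas, 13 of 15 members were higher in fibroblasts than in the remaining cells, with a median log2 ratio of 2.33 over the list. For a list of fibroblast genes this was likely from the start, so it is only weak evidence against RNA of other classes. The median of 2.75 is over all fibroblasts, and most cells of the 2 tissues were in different clusters. In cluster 14, which held cells of both, the list took 0.813% and 0.701% of UMIs in breast and 0.400% and 0.280% in pancreas. These are shares of summed UMIs, not medians of ratios, and the pancreas values rest on 22 and 28 cells. How far the mix of clusters sets the median was not tested. A difference between tumour types remains possible, and with 1 sample per tissue it cannot be told from a difference between people.

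Contractile and matrix genes were higher in breast fibroblasts, with a median of -1.61. With thinning it was -1.65, which does not decide on depth either, since thinning keeps the expected gene shares of each cell. All 18 of 18 members were higher in breast fibroblasts than in the remaining breast cells, by a median log2 ratio of 7.06. For a list of fibroblast genes this was likely from the start, so it is only weak evidence against RNA of other classes. The median of -1.61 is over all fibroblasts, and most cells of the 2 tissues were in different clusters. In cluster 14, which held cells of both, matrix genes took 0.618% and 0.560% of UMIs in breast and 0.679% and 0.503% in pancreas. These too are shares of summed UMIs and not medians of ratios, with 22 and 28 pancreas cells. How far the mix of clusters sets the median was not tested. A difference between tumour types and one between people could each account for the value of -1.61, and the design holds no test between them.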

How the results depend on the processing

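The hashtag group and thinning alternatives, the leaving out of libraries for classes other than fibroblasts and the leaving out of mouse subclusters or their cells were chosen after seeing the data. Of 280 recomputed values of the 20 named fibroblast genes, 236 stayed within the spread, 44 moved and 0 reversed. The smallest absolute log2 ratio was 3.51. Values with no low filter and with no guard could not move, since neither setting changes the ratios. Leaving out 1 library could not reverse a gene, since the rule asked for the same sign in every pair of libraries. The rule named 16 of the same 20 genes with size factors, 15 with no low filter, 14 with no guard, 19 with doublet calls kept, 20 at resolution 2, 19 with stricter fibroblasts, 17 with thinning, 17 with the first and 13 with the second breast hashtag group (373 and 51 cells), 12 with stricter cells, and 16 to 19 when leaving out 1 library. In the other classes, leaving out 1 library could not turn a named gene either, by the same rule. The smallest absolute log2 ratio was then 2.28 in T or NK cells, 3.48 in macrophages and 2.60 in pericytes. Size factors gave medians of 1.095 for steady-state, -1.36 for matrix, 0.11 for focal adhesion and 0.074 for TGF-beta genes, and a pseudocount of 5 gave 2.21 for immune-modulating genes. With thinning, TGF-beta genes were at 0.22, positional factors at -0.27 and lipid-associated macrophage genes at -0.027. In the first hashtag group steady-state genes were at 1.09, immune-modulating at 3.79, matrix at -1.70, positional factors at -0.043 and lipid-associated macrophage genes at -0.10. In the second they were at 2.06 for steady-state, -1.12 for matrix, 0.10 for focal adhesion, 0.44 for hypoxia, 0.89 for TGF-beta, 0.78 for cell-cycle and 0.44 for tissue-resident macrophage genes. Of 120 values of the other lists, 70 stayed, 38 moved and 12 reversed. Thinned to 500 UMIs, matrix scores correlated with steady-state scores at -0.348 and -0.383 and with immune-modulating scores at -0.426 and -0.349 in breast libraries 1 and 2. With 25 genes per mouse subcluster 29.2% of combinations passed, and with 100 genes 58.3%, and without the subclusters of lymphocyte genes 62.5% of combinations passed with 50 genes and 18.8% with 25. With genes of at least 50 CPM the correlations of mouse with human were 0.384, 0.383, 0.363 and 0.365. Without the mouse cells of those subclusters the correlations of mouse with human stayed within the spread (0.645 to 0.657). Fibroblast shares with stricter cells were 9.20, 9.47, 63.1, 65.9 and 34.3%, without those mouse cells 8.87% in mouse, and with doublet calls kept 8.28% in breast library 2. T or NK shares with stricter cells were 0, 0.104, 13.5, 11.8 and 7.47% in the order breast 1, breast 2, pancreas 1, pancreas 2, mouse. For these values the cause was not tested, except that the second hashtag group and the stricter cells hold fewer cells by construction. At 3000 counts per cell, ATAC cells numbered 3043 and formed 16 clusters. No paired analysis was possible because no sample of 1 tissue is matched to a sample of another. The edgeR and DESeq2 tests and the replicate block were not run, since each tissue had 1 sample, nor were windows of 2 or 10 kb around gene starts, since no annotation of mm10 was at hand. Breast fibroblasts, with a median of 1315 UMIs against 11779 in pancreas, limit what can be seen: 3 counts over all breast fibroblasts are 2.73 CPM.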

Other observations

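The comparison by hashtag group was chosen only after the data had been seen, and all values here are given without explanation.

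Hashtag antibody UMIs numbered 1089030 and 1249928 in the breast libraries, 1184155 and 1256171 in the pancreas libraries and 2684146 in the mouse library, with medians of 149, 159, 479.5, 455 and 143 tag UMIs per cell. All 20 named fibroblast genes kept their direction by at least 1 log2 unit in both breast hashtag groups.

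In the mouse tumour library, where B, T or NK and plasma cells were 28.7%, 27.0% and 15.2% of cells, neutrophils, early responders to tissue damage, were 2.90%. With stricter cells these were 23.9%, 7.47%, 15.0% and 0.934%. Macrophages, monocytes and dendritic cells made up 8.42% (3.65% with stricter cells and 5.18% at clustering resolution 2, where cells of unnamed clusters were 4.05% against 0.887%). Red-cell precursors were 1.91% (0.731% with stricter cells) and pericytes or smooth muscle cells 0.439% (0 of 2463 with stricter cells). Mast cells were 0.831% of breast cells, and with stricter cells 0 of 826 and 0 of 961 in the breast libraries.

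Immune-modulating and stress scores correlated across fibroblasts at a Spearman rho of 0.0361 and 0.136 in the pancreas libraries and 0.303 and 0.184 in the breast libraries. In the third of pancreas fibroblasts with the highest stress score the median log2 ratio of immune-modulating genes over breast was 2.39, against 2.54 in the third with the lowest.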
